A study of Homo sapiens with 2 samples.

How the data were processed

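Total RNA from the human ovarian cancer cell line SKOV3 was measured in 2 samples, per the labels: 1 library of untreated parental cells and 1 library of a derivative kept in the PARP inhibitor olaparib for at least 3 months. RNA was taken up in Trizol and depleted of ribosomal RNA before library construction, per the labels' protocols. The submitters' processing notes name the aligner HISAT2 and the assembler StringTie, with versions not given in the sources used here. The same notes name the mouse build mm10, whereas the deposited table carries human Ensembl identifiers and human loci. Of its 47892 transcripts, 43558 (91.0%) were found by identifier in GENCODE release 29, and 98.5% of these had the same GRCh38 start and end there. Coordinates are therefore given as in the deposited table, on GRCh38.

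The deposited table holds 1 normalized expression value per transcript and library, per the file headers, in a unit that the header does not name. The values are called listed values here. They summed to 47632 in the resistant library and 46879 in the parental library. Sequencing depth is unknown, and no read-based interval on a listed value is given. The authors also deposited a log2 fold change (resistant over parental), a p-value and an adjusted p-value per transcript, and the test behind them is not given in the sources used here. Their p-values compare 2 libraries, not 2 conditions, and are quoted as theirs. A second deposited list of 20 transcripts was used only for a comparison with the table.

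By GENCODE release 29, the matched transcripts were mostly non-coding: 21811 (50.1%) were retained-intron transcripts, 14375 (33.0%) processed transcripts without an open reading frame, 3720 antisense RNAs and 2746 lincRNAs, and 55 were protein-coding. The type of the other 4334 transcripts is unknown here. Since 79.7% of the matched transcripts belong to protein-coding genes, the value of such a gene here comes mostly from transcripts annotated as non-coding and does not stand for its mRNA. Some sums, such as that of ATR, include a transcript annotated as protein-coding. No transcript of the mitochondrial chromosome was analysed here.

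The deposited fold changes were compared with the listed values. With a constant of 0.114 added to the resistant and 0.136 to the parental count (mean 0.125), each log2 fold change of 46127 transcripts (96.3%) was the ratio of a pair of whole counts to its last printed digit, with at most 0.01 matches by chance allowed. The 4569 pairs of counts that occurred more than once each had a single p-value. For 10684 transcripts (22.3%) the count was 0 in the resistant (5453) or the parental (5231) library, although each of these listed a value above 0 there. Where the count was over 20, the listed value and the count agreed within 0.3 on the log2 scale in 99.96% of transcripts in each library, with locus length including introns as the length. The ratio of listed values differed by more than 0.3 on the log2 scale from the deposited log2 fold change, after a common offset of −0.28, in 13121 transcripts (27.4%).

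Listed values of all transcripts with the same gene name were summed, giving 16978 genes. The log2 ratio of a gene is log2(resistant value + 1) minus log2(parental value + 1), with a pseudocount of 1 that understates differences of low genes. Genes with a mean of at least 1 over both libraries were called expressed (5767 genes). With 1 library per group no test was made, no p-value was computed, and differences have no replicate check. Genes were counted at a size threshold of 2-fold. For each of 25 gene lists (533 members, of which 358 were matched, also through older symbols from RefSeq), the median log2 ratio of expressed members was placed among 10000 random lists of the same size matched on mean value in 20 bins. Its percentile describes these 2 libraries only. The lists covered homologous recombination, the MRN complex, Fanconi anaemia, end joining, PARP enzymes and base excision repair, replication stress, ABC transporters, proliferation, p53 targets, mesenchymal and epithelial genes, interferon-stimulated genes, NF-kB and cytokine genes, hypoxia and glycolysis, NRF2 targets, stress responses, cholesterol and fatty acid synthesis, xenobiotic metabolism, stem-like and WNT-related genes, ovarian carcinoma identity, histones, mitochondrial mRNAs, ribosomal proteins, and immune, endothelial and fibroblast markers.

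The lists, the thresholds and the rule for named genes were set before the data were examined. By that rule the text names LINC00467, RAD50, MRE11, NBN, PARP1, PARG, ABCB1, ABCG2, SLFN11, TP53BP1 and MIR485 where they have a value. It also names the 15 highest and 15 lowest log2 ratios among expressed genes with a gene symbol and a larger value of at least 5, the 5 highest and 5 lowest long non-coding RNAs under the same filter, and the up to 4 members of each list with the largest absolute log2 ratio (up to 2 for a list within 0.1 of the median of all genes). Long non-coding RNAs were recognised by symbol only, starting with LINC or ending in -AS1, -AS2 or -DT. ABCG2, SLFN11 and MIR485 were not analysed here, and some genes that met the rule are not reported here.

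Alternatives were pseudocounts of 0.1 and 5, rescaling by the median ratio or the upper quartile, no filter or a mean of at least 5, protein-coding genes only, the transcript with the largest mean in place of the sum, and 5 expression bins. Chosen after seeing the data were setting listed values to 0 where the corresponding count was 0, leaving out transcripts whose value ratio and fold change differ, removing the trend of the log2 ratio on GC content (20 bins), and leaving out chromosome 16. The scripts were tested on simulated data. In a simulation of 28082 transcripts, 99.99% of those given a pair of counts had the right pair, with 0 false zeros. The simulated fold changes had the form that the method assumes. From those of the 16978 genes with a mean of at least 5, 200 were changed 4-fold, and 100% of these passed the 2-fold threshold. Genes with lower means were not covered by that check. Of 200 random lists, 4% fell outside the central 95%. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.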

Results

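Parental SKOV3 cells, a human ovarian adenocarcinoma line, were compared with an olaparib-resistant derivative raised by continuous exposure to this inhibitor of the DNA repair enzymes PARP1 and PARP2. Each group had 1 ribosomal RNA-depleted library, so the differences below have no replicate check and describe these 2 libraries. Expression was listed for 47892 transcripts of 16978 genes, most of them non-coding isoforms, and 7228 transcripts in the resistant and 6148 in the parental library reached a listed value of 1. Sequencing depth is unknown.

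The title of the study names LINC00467, a long intergenic non-coding RNA, as a mediator of PARP inhibitor resistance, and its level was compared first. LINC00467 (ENSG00000153363, chromosome 1, 211382736 to 211435333, GRCh38) was higher in the resistant line, at a summed listed value of 7.39 against 3.902 in the parental line, a log2 ratio of 0.78. Of 5767 expressed genes, 84.8% had a lower log2 ratio. The difference came mostly from 1 isoform. LINC00467-206 had a listed value of 3.78 in the resistant and 0.0804 in the parental line and made up 51.2% of the gene's value in resistant cells against 2.06% in parental cells. The most abundant parental isoform, LINC00467-201, a lincRNA in GENCODE, was nearly level at 2.93 and 2.58. Of the other 11 isoforms, 4 were higher in the resistant line, led by LINC00467-222 (0.399 against 0.116), and 7 were lower, among them ENST00000667464 (0.00622 against 0.464), LINC00467-203 (0.0120 against 0.187) and LINC00467-208 (0.00389 against 0.156). In the authors' deposited table LINC00467-206 had a log2 fold change of 16.25 (adjusted p = 9.59e-59), LINC00467-201 one of −0.10 (adjusted p = 0.887) and ENST00000667464 one of −13.51 (adjusted p = 9.62e-38). These fold changes correspond to counts of 8882 and 0 for LINC00467-206, 7284 and 9288 for LINC00467-201, and 0 and 1581 for ENST00000667464. Such counts followed locus length including introns, so they need not be numbers of sequenced reads, and the authors' p-values share this limit. In 7 of the 13 isoforms the count was 0 in either library beside a listed value above 0. With values at a corresponding count of 0 set to 0, the log2 ratio was 0.80. Leaving out discordant transcripts, whose value ratio and fold change differ and which are mostly those with a count of 0, removed LINC00467-206 and gave 0.19, and with the isoform of largest mean alone, LINC00467-201, it was 0.14. Relative to the median of all genes, by rescaling, it was 0.58.

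**Figure D1:**
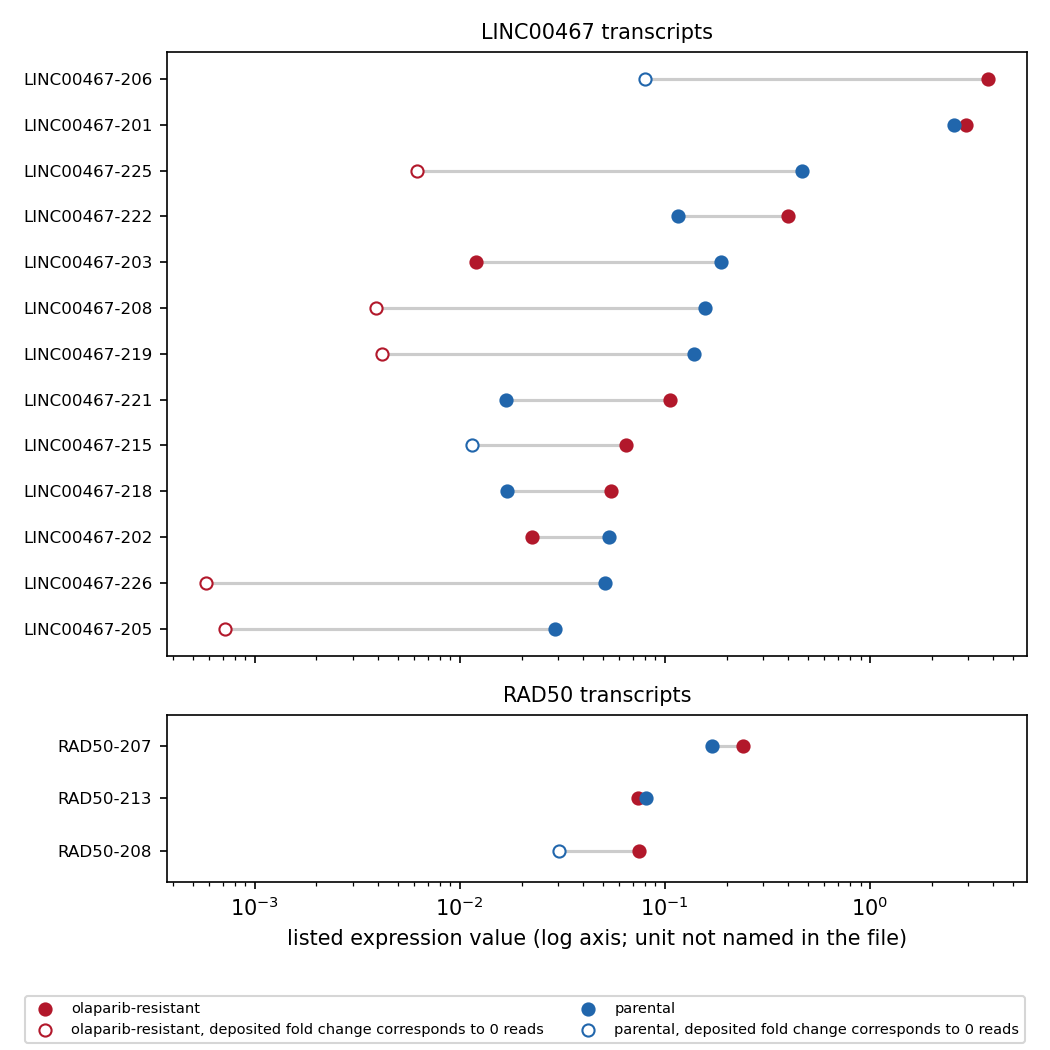
Listed values of each LINC00467 and RAD50 transcript (log axis, unit not named in the file) in the olaparib-resistant library (red) and the parental library (blue), 1 library each, with open points where the deposited fold change corresponds to a count of 0. LINC00467-206 lies at 3.78 in the resistant library and LINC00467-201 at 2.93 and 2.58 in the resistant and parental libraries.

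RAD50, a subunit of the MRN complex that binds and processes DNA double-strand breaks, is the other gene in the study's title. Its 3 listed transcripts (ENSG00000113522, chromosome 5, 132557257 to 132604034) lay below the expression threshold together, with a summed value of 0.390 in resistant and 0.281 in parental cells and a log2 ratio of 0.12. The retained-intron transcript RAD50-207 had 0.242 against 0.169, RAD50-213, whose type is unknown here, had 0.0740 against 0.0810, and the processed transcript RAD50-208 had 0.0748 against 0.0304, where the fold change corresponds to counts of 29 and 0. In the authors' deposited table RAD50-207 had a log2 fold change of 0.22 (adjusted p = 0.758), RAD50-213 one of −0.41 (adjusted p = 0.477) and RAD50-208 one of 7.995 (adjusted p = 1.5e-06). The sign of the RAD50 log2 ratio turned, to −0.19, once the trend on GC content was removed. That trend was taken from expressed genes and RAD50 lay below the threshold, so the turn says little about RAD50.

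Of the partners of RAD50, MRE11, the nuclease of the complex, lay below the expression threshold at 0.894 in resistant and 0.557 in parental cells (log2 ratio 0.28). With its 1 transcript that corresponds to a parental count of 0 set to 0 there, the MRE11 ratio was 0.65. NBN had 2.04 against 1.54 (0.26), close to the median of all genes of 0.16, and its ratio was 0.12 after rescaling by the median ratio and 0.08 with the trend on GC content removed. PARP1, the main target of olaparib, had 1.88 against 2.32 (−0.21), and PARG, which removes poly(ADP-ribose), had 0.697 against 1.04 (−0.27). TP53BP1, whose loss restores homologous recombination in BRCA1-deficient cells, had 2.66 against 2.76 (−0.04). ABCB1, a drug efflux pump known to export olaparib, had 2 listed transcripts, a retained-intron and a processed transcript, with a sum of 0.00208 in resistant and 0.108 in parental cells (−0.15). Both correspond to a count of 0 in the resistant library, and the mRNA of ABCB1 was not analysed here.

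Across 5767 expressed genes, 490 (8.50%) were at least 2-fold higher and 252 (4.37%) at least 2-fold lower in the resistant line, and 5025 lay between. HIGD1A, a mitochondrial protein induced by hypoxia, had the largest difference upward, with a listed value of 58.8 against 1.54 (log2 ratio 4.56). SOD2, the mitochondrial superoxide dismutase, had 35.6 against 2.29 (3.47), and YAP1, the transcriptional effector of the Hippo pathway, had 14.8 against 0.525 (3.37). The cytokine IL6 had 9.35 against 0.233 (3.07) and the secreted chaperone CLU had 13.2 against 0.906 (2.90). Also among the 15 highest were ATP6AP2, GDI2, KIAA1191, HSD17B11, LYPLA2, DHX40, DDX56, MKLN1 and HTATIP2, with log2 ratios between 2.94 (HTATIP2) and 3.81 (ATP6AP2). The values of SOD2 and ATP6AP2 rest on transcripts whose parental count corresponds to 0. With these parental values set to 0 the log2 ratios were 4.05 and 4.04, and with the transcripts left out, which removes the difference itself, 0.52 and 0.34.

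Among genes lower in the resistant line, the replication-dependent histone gene HIST1H3J had 0.264 against 866 (log2 ratio −9.42), from 1 transcript of a multicopy family in which reads can be shared. PHB2, a mitochondrial prohibitin, had 20.03 against 225.9 (−3.43), PTMA, which encodes prothymosin alpha, had 14.2 against 145.9 (−3.27), and the ribosomal protein gene RPL14 had 15.1 against 110.8 (−2.80). COQ9, needed for coenzyme Q synthesis, had 4.84 against 60.2 (−3.39). CIAO2B, of cytosolic iron-sulfur cluster assembly, had 1.31 against 24.0 (−3.44). SLC45A4, HAUS1, MRPL18, GCH1, IL10RB, CYSTM1, CTBP1, MRPL9 and KCNK15-AS1 completed the 15 lowest, with log2 ratios between −3.76 (SLC45A4) and −2.60 (KCNK15-AS1). The only SLC45A4 transcript corresponds to a resistant count of 0, and its log2 ratio was −4.06 with that value set to 0. In that setting MRPL18, with 2 such transcripts, was at −3.78. MRPL9 was at −2.73 with its resistant value at a count of 0 set to 0, and at 0.25 with that transcript, which carries the difference, left out. The median log2 ratio of expressed genes was 0.16, and after rescaling by the median ratio 342 genes were at least 2-fold higher and 362 at least 2-fold lower, so that the share of higher genes among those past the threshold went from 66.0% to 48.6%. With a pseudocount of 0.1 the counts were 957 and 434, with a pseudocount of 5 they were 104 and 68, and with a mean of at least 5 they were 198 and 102.

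**Figure D2:**
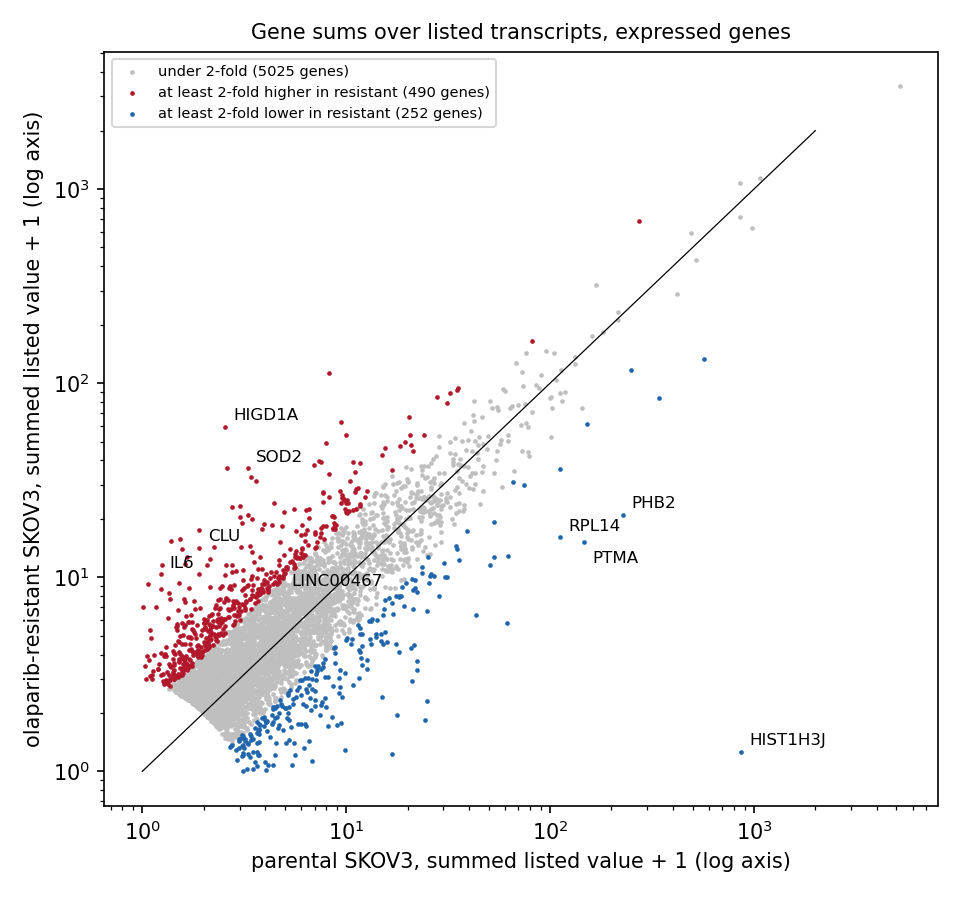
Summed listed value plus 1 of each expressed gene in the parental (x axis) and olaparib-resistant library (y axis), both log axes, 1 library each, with the line of equal values. Of 5767 genes, 490 lie at least 2-fold higher (red) and 252 at least 2-fold lower (blue) in the resistant line, with HIST1H3J farthest from the line.

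Long non-coding RNAs were taken by symbol, starting with LINC or ending in -AS1, -AS2 or -DT. Others, such as GAS5 and the SNHG genes, were outside this set. Those in the set with a larger value of at least 5 numbered 57, of which 4 were at least 2-fold higher and 6 at least 2-fold lower. Their median log2 ratio was −0.06. The antisense RNA NNT-AS1 was highest, at 6.05 in resistant and 0.00992 in parental cells (log2 ratio 2.80), followed by MAP3K14-AS1 with 5.94 against 1.27 (1.61), LINC00847 with 7.39 against 2.77 (1.16), TTN-AS1 with 8.01 against 3.20 (1.10) and LINC02593 with 22.8 against 11.9 (0.88). LINC00467 ranked 6 from the top of these 57. The lowest were KCNK15-AS1 with 0.125 against 5.81 (−2.60), LINC00963 with 3.79 against 12.1 (−1.45), NUP50-DT with 2.08 against 7.11 (−1.40), LINC01089 with 3.76 against 9.0004 (−1.07) and ASB16-AS1 with 2.47 against 6.30 (−1.07). ASB16-AS1 turned to 0.51 when values with a corresponding count of 0 were set to 0. The strand used in counting is not given, so an antisense RNA and its partner may share reads.

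Of 20 gene lists with at least 3 expressed members, 5 lay outside the central 95% of random lists, and 3 of these were higher in the resistant line. For lists of genes drawn at random 1 would be outside. Members of a list may vary together between any 2 cultures, so more than 1 may be outside without an effect of resistance. NF-kB and inflammatory cytokine genes had a median log2 ratio of 2.22 over 5 expressed members (2.05 above the median of all genes, percentile 99.99), with SOD2, IL6 and the prostaglandin synthase PTGS2 (5.19 against 0.332, log2 ratio 2.22) at least 2-fold higher and the inhibitor NFKBIA at 33.4 against 27.6 (0.27). Both listed PTGS2 transcripts correspond to a parental count of 0, and the PTGS2 log2 ratio was 2.63 with their parental values set to 0. Homologous recombination genes had a median of 0.71 over 11 expressed members (0.55 above all genes, percentile 99.4), and 10 of the 11 were above the median of all genes. RAD51C had 8.15 against 2.48 (1.40) and RAD51B 4.09 against 1.40 (1.08), while RAD52 had 3.00 against 1.14 (0.90) and the helicase HELQ 2.17 against 0.732 (0.87). Their transcripts of known type were retained-intron or processed transcripts, so these values do not stand for the mRNAs. Mesenchymal genes had a median of 0.77 over 6 expressed members (0.61 above all genes, percentile 98.9), with 3 above and 3 below the median of all genes, so that the median falls between 2 groups. At least 2-fold higher were the matrix genes FN1 (10.5 against 1.09, 2.46), COL6A1 (4.54 against 0.466, 1.92) and TGFBI (4.91 against 1.06, 1.52), with the fibronectin receptor subunit ITGA5 at 2.37 against 2.91 (−0.21). With no filter on low values the NF-kB median was 0.44 over 17 members and the homologous recombination median 0.26 over 31. With values at a corresponding count of 0 set to 0, the NF-kB median was 2.63 and the mesenchymal median 0.80 (percentile 98.9). Leaving out discordant transcripts, a filter that removes isoforms of SOD2, PTGS2, FN1 and TGFBI because they differ, gave 0.40 (percentile 79.97) and −0.19 (percentile 8.91). The mesenchymal median was 0.09 over 14 members with no filter on low values (percentile 69.4). With the trend on GC content removed, the homologous recombination median was 0.42 (percentile 89.9), and with a mean of at least 5, which left 3 members, its percentile was 89.5.

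Cholesterol and fatty acid synthesis genes were lower in the resistant line, with a median log2 ratio of −0.63 over 15 expressed members (−0.80 relative to all genes, percentile 0.01), and 14 of the 15 were below 0. The mevalonate pathway enzymes MVD and MVK had 4.21 against 14.4 (−1.57) and 0.890 against 3.49 (−1.25), and the fatty acid synthase FASN had 3.95 against 13.1 (−1.51). For these genes, too, the transcripts of known type were retained-intron or processed transcripts, not mRNAs. The cholesterol list stayed outside the central 95% in each of the 13 alternatives. Proliferation genes had a median of −0.43 over 19 expressed members (−0.59 relative to all genes, percentile 0.02), of which 14 were below 0. The replicative helicase subunit MCM7 had 60.5 against 151.5 (−1.31) and the mitotic kinesin KIF20A 0.798 against 2.36 (−0.90), whereas TYMS, the thymidylate synthase, had 13.2 against 5.09 (1.22) and the checkpoint kinase BUB1 21.3 against 9.86 (1.04). With a mean of at least 5, which left 6 members, the proliferation percentile was 3.58. The proliferation median was −0.19 over 27 members with no filter on low values (percentile 0.41).

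**Figure D3:**
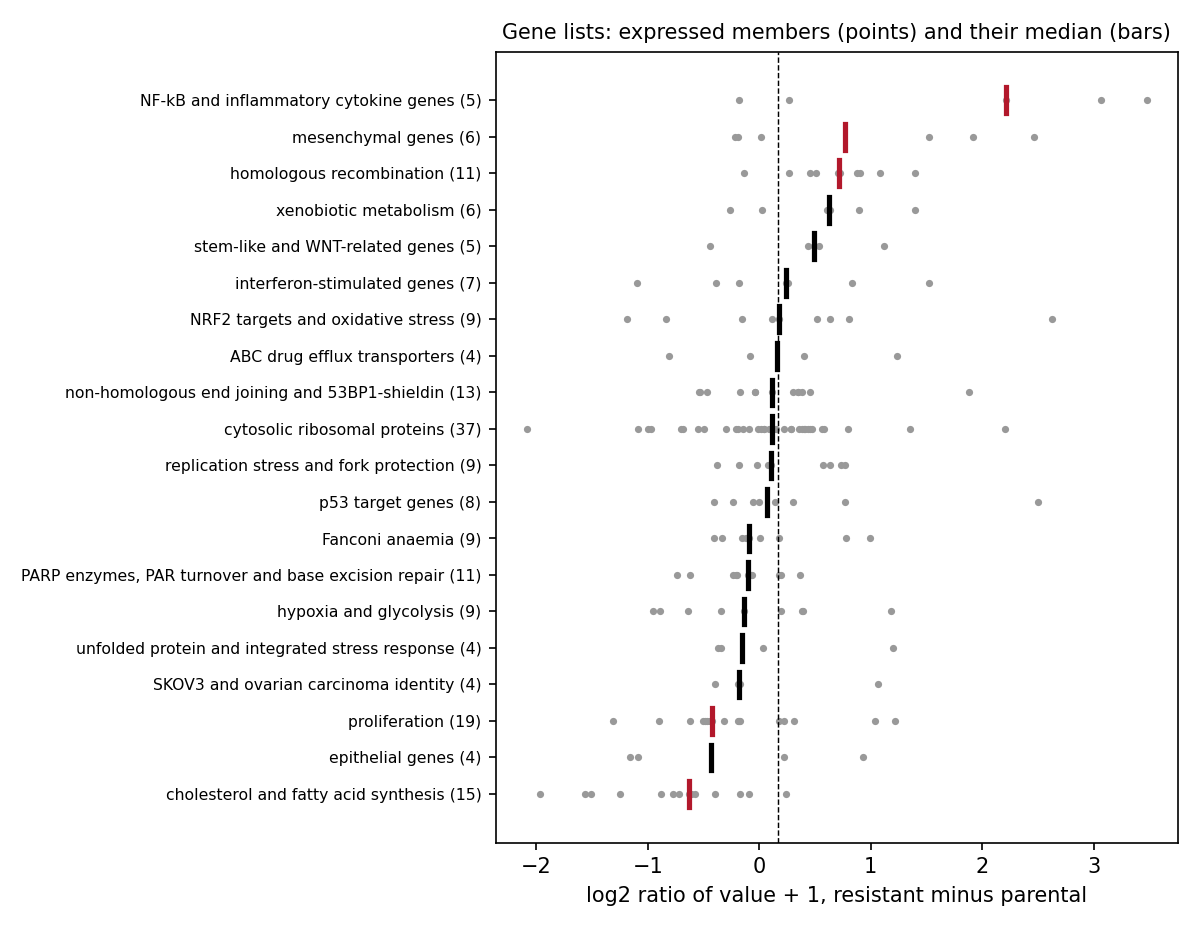
Log2 ratio of value plus 1, resistant minus parental, of the expressed members (grey points) of 20 gene lists and their median (bars, red where outside the central 95% of random lists), with the number of members in brackets and a dashed line at the median of all expressed genes. The NF-kB list has a median of 2.22 and the cholesterol list one of −0.63.

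The other DNA repair and drug response lists lay within the central 95% of random lists. Fanconi anaemia genes had a median log2 ratio of −0.09 over 9 members, with FANCL at 0.995, FANCI at 0.78, FANCA at −0.41 and FAN1 at −0.34. End joining and 53BP1-shieldin genes had 0.11 over 13 members, with the ubiquitin ligase RNF8 at 1.88 (5.38 against 0.729) and DYNLL1 at −0.54. PARP enzymes and base excision repair genes had −0.11 over 11 members, with APEX1 at −0.74, CHD1L at −0.62 and POLB at −0.24. Replication stress genes had 0.11 over 9 members, with ZRANB3 at 0.77 and the kinase ATR at 0.73. ABC transporters had 0.16 over 4 members, with ABCC3 at 1.23 and ABCC4 at −0.81. The MRN complex had 1 expressed member, NBN. With the transcript of largest mean per gene, the Fanconi median turned to 0.66 (4 members) and the end joining median to −0.09 (9 members). The Fanconi median was also above 0 with a mean of at least 5 (0.17, 3 members), and the end joining median below 0 with no filter (−0.03). The PARP and base excision repair median was above 0 with the GC trend removed (0.06). It was 0.37 with a mean of at least 5 (1 member).

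Several single genes stood apart within lists whose medians did not. In the p53 target list (median 0.07 over 8 members) the death receptor FAS had 6.76 against 0.373 (2.498) and MDM2 had a log2 ratio of 0.77. In the NRF2 list (0.17 over 9 members) the ferritin heavy chain FTH1 had 48.2 against 6.97 (2.63) and PGD had −1.19. In the epithelial list (−0.43 over 4 members, percentile 6.93) KRT18 had −1.16, ESRP2 −1.08, KRT8 0.93 and KRT7 0.22. In the hypoxia and glycolysis list (−0.14 over 9 members) P4HA2 had 1.18, LDHA −0.96, NDRG1 −0.89 and ENO1 −0.64. In the unfolded protein and integrated stress response list (−0.15 over 4 members) HSP90B1 had 1.20, HERPUD1 −0.37, XBP1 −0.34 and PHGDH 0.04. In the interferon list (0.24 over 7 members) IFI44 had 1.52 and CMPK2 −1.09. In the xenobiotic list (0.62 over 6 members, percentile 94.7) AHRR had 1.40, GSTM3 0.89, NNMT 0.64 and CYP1B1 0.61, and the list lay outside the central 95% with a pseudocount of 5 (percentile 99.6) and with the GC trend removed (98.3). GSTM3 was at 1.37 with its parental value at a count of 0 set to 0. In the stem-like list (0.49 over 5 members) CD44 had 1.12, HES1 0.53, BMI1 0.49 and DKK1 −0.44. In the ovarian carcinoma list (−0.18 over 4 members) CCNE1, which encodes cyclin E1, had 1.07, ERBB2 −0.40, ARID1A −0.19 and ERBB3 −0.17. Ribosomal protein genes had 0.11 over 37 members, with RPS6 at 2.21 and RPL13 at −2.08, and their median turned to −0.11 after rescaling by the median ratio, as the medians of the end joining, replication stress, p53 and NRF2 lists also turned below 0. The epithelial median turned to 0.22 with chromosome 16 left out or a mean of at least 5, and to 0.45 with the transcript of largest mean (3 members each). The interferon median turned to −0.20 with the transcript of largest mean and −0.39 with a mean of at least 5 (1 member), and the stem-like median to −0.44 with a mean of at least 5 (1 member). The stress response median was above 0 in 4 alternatives, from 0.04 with chromosome 16 left out or a mean of at least 5 to 0.08 with the transcript of largest mean and 0.20 with no filter. The hypoxia median was 0.03 with chromosome 16 left out and the ovarian carcinoma median 0.04 with no filter, 0.58 with the transcript of largest mean (2 members) and 1.07 with a mean of at least 5 (1 member). Of the endothelial and fibroblast markers 4 were listed and 0 were expressed, and 0 immune markers, 0 histones of the fixed list and 0 mitochondrial mRNAs were listed.

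Of all transcripts in the authors' deposited table, 21957 had an adjusted p-value below 0.05, of which 11283 had a log2 fold change above 0 and 10674 one below 0. Of these 21957 transcripts, 8851 correspond to a count of 0 in either library. The log2 fold changes of the authors' deposited table ran from −18.7 to 18.0, and 2844 of the 2857 with an absolute value of at least 10 correspond to a count of 0 in either library. The second deposited list held 20 transcripts, LINC00467-206 among them, with the same fold changes as the table. For 8 of these the listed value differed between list and table in at least 1 library. SOD2-212 had a resistant value of 3.44 in the list and 33.4 in the table, and ATP6AP2-210 had 3.93 and 33.9. The parental value of SLC45A4-206 was 8.73 in the list and 15.7 in the table. For these values the table matched the counts behind the fold changes. In 5 transcripts a value at a count of 0 differed, which no count can check. An example was the parental value of SOD2-212, at 0.583 in the list and 1.08 in the table.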

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

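The alternatives that use counts of 0, discordant transcripts, GC content or chromosome 16 were chosen after seeing the data, and the cause of the shifts below was not tested except where named. No paired analysis was possible because each group had 1 library and no test was made. With a pseudocount of 0.1, 957 genes were at least 2-fold higher and 434 lower, and with one of 5, 104 and 68. With a mean of at least 5, which leaves 1609 of 5767 genes, the counts were 198 and 102 and 1 list was outside the central 95% of random lists. The other alternatives gave 342 to 529 higher and 193 to 362 lower genes. The LINC00467 log2 ratio (0.78) was 0.90 and 0.48 with pseudocounts of 0.1 and 5, 0.58 and 0.59 after rescaling by the median ratio and the upper quartile (which move the median of all genes by −0.16), 0.14 with its isoform of largest mean, 0.19 without discordant transcripts and 0.58 with the GC trend removed. Setting values with a count of 0 to 0 gave 0.80. The RAD50 log2 ratio (0.12) was 0.36 with a pseudocount of 0.1 and −0.19 with the GC trend removed. The latter says little, since the trend came from expressed genes and RAD50 was not among them. Of discordant transcripts with known counts 78.7% have a count of 0, so leaving them out removes differences by its design and says little about stability. It left 3 lists outside and turned the mesenchymal median to −0.19 and MRPL9 to 0.25, which were 0.80 and −2.73 with values at a count of 0 set to 0. ASB16-AS1 turned to 0.51 in that setting. Of 39 named genes, 11 crossed 2-fold in at least 1 alternative (21 of 446 comparisons, and 2 more turned), a share that says little about stability because most were picked as the largest ratios. For LINC00467 and RAD50 a shift was counted when it passed the 95% binomial interval of the corresponding counts, which covers counting error only and is too narrow because these counts scale with locus length. Depth is unknown, so no limit from depth can be given.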

Other observations

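The tests of evenly spread stand-in values and of locus length as the source of the counts were chosen only after the result was seen, as were the groups in the next paragraph and the split of the parental zeros by the size of their counts.

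Long non-coding RNA genes that host small nucleolar RNAs had a slightly lower median in the resistant line, with members on both sides. Of 21 expressed members (the SNHG genes and GAS5), 12 were below 0 and 9 above. The median log2 ratio was −0.24, at percentile 1.35 of random lists matched on mean value, with 0 members at least 2-fold higher or lower. SNHG30 had 5.28 against 10.6 (−0.88), SNHG7 17.8 against 32.7 (−0.85) and SNHG17 4.23 against 7.44 (−0.69), whereas SNHG21 had 3.18 against 1.75 (0.60), SNHG1 13.7 against 9.44 (0.50) and GAS5 49.97 against 38.8 (0.36). Among single transcripts with a mean of at least 1, retained-intron transcripts had a median log2 ratio of 0.19 (4123 transcripts), processed transcripts 0.14 (1659), antisense RNAs −0.06 (277) and lincRNAs −0.12 (232). The random lists were not matched on transcript type, so percentile 1.35 does not set these hosts apart from other long non-coding RNAs.

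The 355 expressed genes of chromosome 16 had a median log2 ratio of −0.22, which is −0.38 relative to all genes, and 73.5% of them lay below the median of all genes; COQ9, CIAO2B, MVD and RPL13 are on this chromosome. Log2 ratios were lower at higher GC content across genes (Spearman rho −0.31, genes not being independent replicates), but with that trend removed the difference of chromosome 16 was still −0.311, whereas that of chromosome 19 went from −0.15 to −0.00416; smaller differences stayed for chromosomes 10 (−0.157), 2 (0.104), 3 (0.106) and 7 (0.0794), each outside the central 95% of random gene sets. Without transcripts with a corresponding count of 0 it was −0.365. Both arms were below all genes (−0.25 for 185 genes of 16p and −0.50 for 170 genes of 16q), and 92.86% of 14 windows of 25 neighbouring genes were below the median of all genes, against 45.7% of 208 windows elsewhere. The GC trend was not removed from these arm and window values, so it may make up part of them. Fewer copies of chromosome 16 in the resistant line may account for part of the difference, a hypothesis that no DNA measurement here tests.

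Values above 0 in a library with a corresponding count of 0 concerned 10684 transcripts, LINC00467-206 among them. Values too small to give a count are argued against, since 64.79% of these values correspond to a count of 1 or more at the scale of their library. That scale uses locus length including introns, so it cannot give numbers of sequenced reads. For the 5453 transcripts with a count of 0 in resistant cells, the parental value divided by the listed resistant value was spread evenly from 2.04 to 99.97 (largest gap to an even spread 0.01124), and for the parental zeros, leaving out the 200 with the largest counts, the reverse ratio was spread evenly from 0.201 to 11.99 (0.01227). For the 100 parental zeros with the largest counts, LINC00467-206, SOD2-212 and ATP6AP2-210 among them, the ratio ran from 2.94 to 99.35 (gap 0.0674). In the resistant library 5466 values had more than 6 decimals, and these included all 5453 at a count of 0. Those values were thus written differently from most others. In the parental library 5 values had more than 6 decimals. In each of the 3 groups the gap was under the 95th percentile of simulated even draws of the same number (0.0183, 0.0192 and 0.128), so numbers drawn evenly between fixed limits may stand in for these zeros, and no biological explanation was tested.

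The deposited log2 fold changes of at least 10 in size sat in transcripts with a median locus length of 39191 bases, against 5734.5 for all. The scale between listed value and count was constant with locus length including introns (interquartile range of its log2 0.001923 in resistant cells) and not with spliced length (2.75), so the counts may have been built from locus length, which enlarges the fold changes and lowers the p-values of long loci with a count of 0. Whether longer loci also differ more in the listed values was tested on transcripts with both counts above 0 (0.2066 larger in median absolute log2 ratio), which hold 2 of the 2857 fold changes of at least 10, so that test decides nothing about them. The scale above shows that the counts follow locus length, which thus enters the size of the 2844 such fold changes with a count of 0. Their listed values in the other library were also higher, at a median of 0.195. At a count of 0 and a smaller fold change that median was 0.048. Whether longer loci also differ more in the listed values stays open for them. No biological explanation was tested.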
